A study of Zea mays with 10 samples.

How the data were processed

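The deposited data were log2 ratios of the 2 channels of 10 cDNA arrays, 1 value per spot, and per the labels' protocols poly(A) RNA was purified from pooled total RNA of at least 3 extractions per genotype. For each labelling, 1 microgram of this RNA was reverse transcribed separately with Cy3 or Cy5. The values had been normalized by the authors before they were deposited, since every array's median lay within 0.001 of 0; the scanner, background correction, normalization and spot filter are not given in the sources used here. Channel intensities were not analysed here. Missing spots were kept missing. Per the design text, the hybrid served as common reference. The reversed arrays were used as deposited. Forward and reversed B73 arrays correlated positively, as arrays turned to one direction before deposit would, but a repeated dye bias on arrays not turned would give this too. The H99 arrays gave no answer, since both orientations hardly correlated. The scale is log2 per the design text, and the direction of the ratio stays unknown.

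Each successive group of 3 spots was treated as 1 clone and averaged. This was decided from the files after they were seen, because each annotated group of 3 carried 1 accession, and because neighbouring spots of one group correlated at 0.755 to 0.922 on the 10 arrays, against 0.196 to 0.391 for neighbours from different groups. The analysis had been planned per probe, and the counts per single spot are given with the alternatives. Gene names came from the platform annotation, which is old. Of 5400 clones, 811 had 1 gene name, 4589 had none and 0 had several, and 208 of the 213 genes were found in the RefSeq table of Zm-B73-REFERENCE-NAM-5.0, used only for names. A clone was tested if it had at least 3 values per inbred with at least 1 in each dye orientation, which left 5357 clones and took out 43.

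The tests were fixed before the data were examined. The plan was to turn every array to one direction and to check the deposited direction by correlating forward and reversed arrays. Using the reversed arrays as deposited was decided after this check, which gave no answer for H99. All 10 arrays were fitted in limma 3.58.1 (R 4.3.3) with a mean per inbred and no dye term, so that both inbreds shared 1 estimate of the spread, with p-values adjusted by Benjamini and Hochberg at 0.05. The contrasts were L1, L2, d and a as in the design text, which used SAM and an F-test in place of limma. Dominance classes came from a 95% Fieller interval of the ratio of d to the size of a, from the moderated variance, among clones called for a. Errors given as SD are between arrays, and those given as SE come from limma. On simulated data with 5357 clones and known changes of 0.25 in log2, 62.7% of the changed clones were recovered for L1, 55.2% for L2, 97% for d and 98.5% for a; all changes of 0.5 and 1 were recovered. Among calls 5.4%, 6.1%, 4.8% and 8.7% were false. Of 200 clones made additive, 94.5% were placed in that class, as were 96% of the dominant and 97.5% of the overdominant ones. Each of these had at least 1 log2 value several times the SD over the real clones, 0.229 for L1 and 0.112 for L2. All the dominant ones were made like B73, the rarer kind in the results. These shares are therefore not the accuracy of the classes reported below. The simulated errors were independent between arrays.

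Gene lists were tested with cameraPR on limma's moderated statistics, with a preset correlation of 0.01, adjusted over lists within each contrast, for lists of at least 5 clones. The list themes and search expressions were also fixed beforehand. The annotation held symbols without descriptions, so that the expressions matched only 15 of 213 names; 148 genes were therefore assigned by hand to 23 lists from their symbols, before any value of a named gene was seen. HMG and other chromatin proteins, and growth regulators, were added as themes at that step. Of the lists, 17 were tested. The other 6, which were cell wall, phenylpropanoid and flavonoid, hormones, growth regulators, kernel and endosperm markers, and anther and pollen markers, had fewer than 5 clones.

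Genes named in the text followed a rule fixed beforehand. For each contrast it took the 8 named clones per sign with the largest called value and one sign on every array (for a, no overlap between the B73 and the H99 arrays), 1 clone per gene, and for each list up to 2 genes with the lowest p. Clones of the first part were thus selected to be stable, and those of the lists for a low p. Gene means over clones, and the grouping of alpha-tubulin and GAPDH clones, were examined after the values were seen.

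Agreement between clones of one gene was measured by the intraclass correlation over genes with at least 3 clones, with 10000 shuffles of gene names for a one-sided permutation p and 2000 bootstrap draws over genes. Print positions were inferred from the row order as 8 blocks, and as an added alternative the median of the clones up to 3 positions away in all blocks was subtracted from each value. Other alternatives were a dye term, other scalings and filters, leaving out each array, the replicate number as a block, each clone's own variance, array weights, separate or robust fits, a threshold of 0.10, averaging by gene and a 99% interval. Added after the data were seen were single spots, subtraction of neighbours, forward or reversed arrays alone, reversed arrays turned for 1 or both inbreds, and lists on gene means. No column of values was left out.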

Results

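The series compared immature ears of maize between the inbred lines B73 and H99 and their F1 hybrid, which is known for heterosis, the better performance of a hybrid than of its parents. RNA came from ears at stage V15, as a bulk of 10 plants per genotype. Each of the 10 cDNA arrays carried the hybrid in one channel and an inbred in the other, with 5 arrays for B73 and 5 for H99. On 3 arrays of each set the dyes ran in the forward orientation, and on 2 in the reverse. The arrays held 16200 spots, read here as 5400 EST clones of 3 neighbouring spots, and 811 clones carried 1 of 213 gene names. Between 0.25% and 2.31% of the spots of an array had no value, and the array medians lay between -0.001 and 0. All values are deposited log2 ratios: L1 is the mean over the B73 arrays and L2 that over the H99 arrays. Which genotype stood in the numerator of the deposited ratio is not settled by the sources. Under the ratio of F1 to inbred that the design text defines, a positive L1 or L2 means a higher level in the hybrid, but the opposite cannot be ruled out, so signs are given without a direction. Whether the reversed arrays were turned to one direction before deposit is not stated either; they were used as deposited, and all 4 contrasts rest on that. As deposited, 2235 clones passed for L1, 66 for L2 and, for the parameters d and a defined below, 1352 and 1089. With the reversed arrays of B73 turned these counts were 0, 13, 2 and 2, with those of H99 turned 2215, 41, 666 and 1516, and with those of both inbreds turned 0 in all 4. Arrays of one set were separate labellings of the same RNA pools, so that p-values measure the spread of labelling and hybridisation and not that between plants. The number of arrays limits the precision.

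The comparison of the hybrid with B73 asked which transcripts differ between the F1 and this parent. The aquaporin PIP2-1, a water channel of the plasma membrane, had the same sign in all 6 of its clones, with a gene mean of -0.29 ± 0.095 (SD, n = 5 arrays; limma adjusted p = 0.000844). GPC1, a cytosolic glyceraldehyde-3-phosphate dehydrogenase of glycolysis, had a mean of -0.16 ± 0.055 over 10 clones (SD, n = 5; limma adjusted p = 0.0345), with 7 clones negative. The single clone of the MADS-box gene ZAG3, a member of a family of flower regulators, lay at 0.32 ± 0.024 (SD, n = 5; limma adjusted p = 0.000435). Single clones of other genes reached larger values. A clone of the heat shock gene hsp70-5 lay at -1.04 ± 0.48, one of sam2, an S-adenosylmethionine synthetase, at -0.98 ± 0.28 and one of the alpha-tubulin tua3 at -0.94 ± 0.36 (SD, n = 5 each), but the means over all clones of these genes were only -0.10, -0.07 and -0.10. RP-P0, an acidic ribosomal protein, was called in both directions, with 1 clone at -0.64 ± 0.22 and another at 0.50 ± 0.15 (SD, n = 5 each).

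In all, 2235 of 5357 tested clones (41.7%) passed an adjusted p of 0.05 for L1, 1126 with a positive and 1109 with a negative value. These values repeated between arrays, with correlations across clones of 0.76 to 0.82 between forward arrays and of 0.37 to 0.54 between forward and reversed ones. They were not shared by clones of the same gene. Over 624 clones of the 70 genes with at least 3 clones, the intraclass correlation of L1 within genes was -0.007 (95% bootstrap interval over genes -0.051 to 0.037; permutation p = 0.62), and the SD within genes, 0.235, was as large as that over all clones, 0.229. None of the 16 named clones with the largest L1 of either sign belonged to a gene whose several clones all had that sign. The 17 gene lists tested gave no call for L1, with adjusted p of 0.482 or more, although several held many called clones. Of 56 clones of chaperone and heat shock genes, 20 were negative and 9 positive (32 called when adjusted over the list alone), and of 42 clones of MADS-box and other inflorescence regulators 16 were positive and 5 negative (22 adjusted over the list alone). The count fell to 1467 without B73 array 1 and to 1398 without B73 array 3, and to 1142 with all arrays scaled to one spread. When the clones of a gene were averaged, 65 of 213 named genes passed, and 56 when adjusted over the named genes alone.

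**Figure D1:**
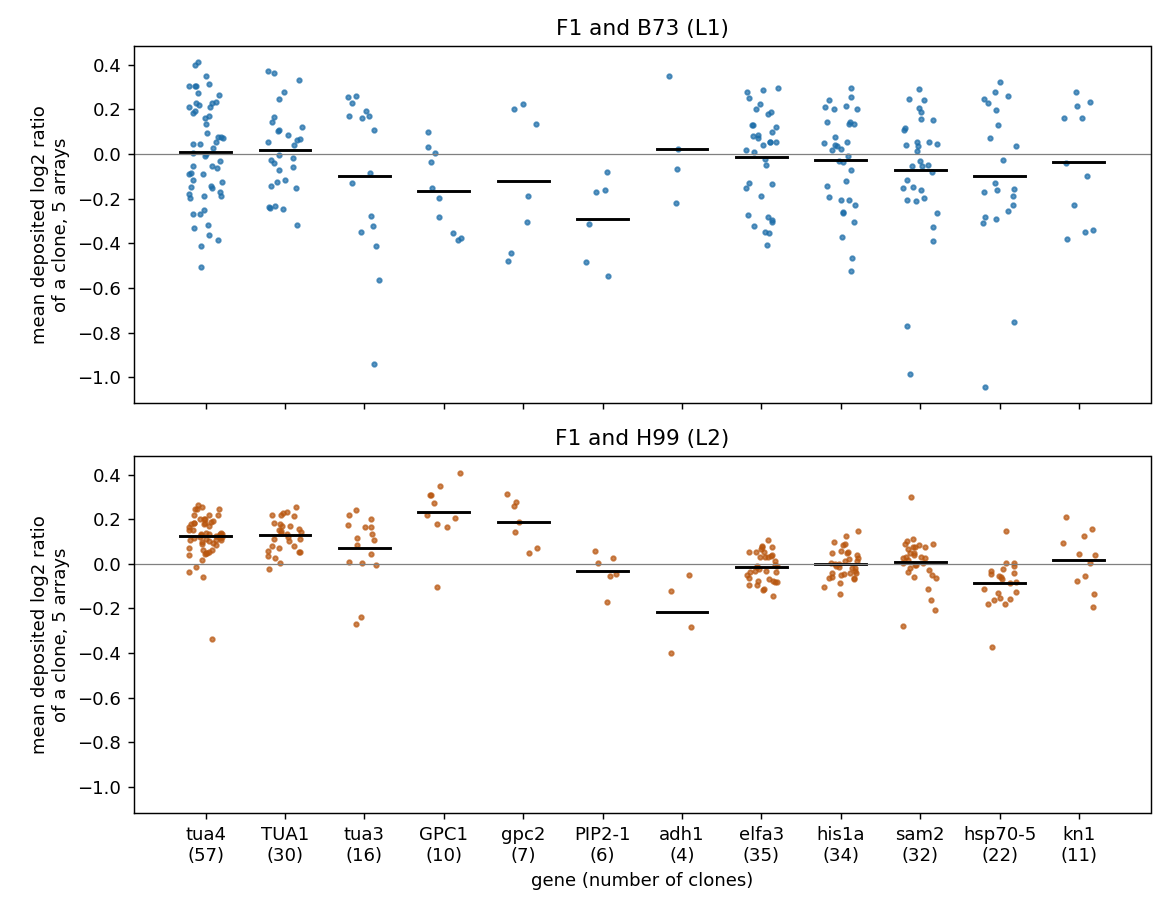
Mean log2 ratio of every clone of 12 genes, for the F1 and B73 (upper panel, L1) and the F1 and H99 (lower panel, L2). Each point is 1 clone averaged over 5 arrays, the black line is the mean over clones, and numbers in brackets count clones. The clones of tua4, TUA1, GPC1 and gpc2 lie mostly above 0 for H99, and clones of most genes scatter on both sides of 0 for B73.

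The comparison with H99 asked the same of the other parent. Alpha-tubulins, the subunits of microtubules, had mostly positive clones in 3 of 5 genes. In tua4, 53 of 57 clones were positive, with a gene mean of 0.12 ± 0.046 (SD, n = 5 arrays), and in TUA1 29 of 30, with 0.13 ± 0.059 (SD, n = 5). In tua3 13 of 16 clones were positive, with a mean of 0.07, in tua5 4 of 8, with 0.02, and in tua6 3 of 4 were negative, with -0.07. The list of tubulins and actins, 121 clones of 10 genes, had a median L2 of 0.115 and a cameraPR adjusted p of 7.2e-12. With an estimated correlation between its clones the adjusted p = 0.0399, and with the clones of each gene averaged the adjusted p = 0.932. Only 1 clone of the list passed alone (25 adjusted over the list alone), and no gene mean of an alpha-tubulin passed, the lowest limma adjusted p being 0.25 for tua4 and 0.247 for TUA1. Paralogous tubulins may share hybridisation signal, so that values of single family members are uncertain.

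The list of glycolysis and fermentation was called as well, although none of its gene means passed and these had both signs. All 7 clones of gpc2 and 9 of 10 clones of GPC1, both glyceraldehyde-3-phosphate dehydrogenases, were positive, with gene means of 0.19 ± 0.079 and 0.23 ± 0.14 (SD, n = 5 each; limma adjusted p = 0.0989 and 0.067). All 4 clones of adh1, the alcohol dehydrogenase of fermentation, were negative, with a mean of -0.21 ± 0.11 (SD, n = 5; limma adjusted p = 0.0735). The 8 named clones that passed were 3 of GPC1, the highest at 0.41 ± 0.26, and 1 each of gpc2 at 0.32 ± 0.19, adh1 at -0.40 ± 0.12, sam2 at 0.30 ± 0.16, HD6 at 0.27 ± 0.12 and TUA1 at 0.23 ± 0.066 (SD, n = 5 each). The mean over all 32 clones of sam2 was only 0.01 (limma adjusted p = 0.96). The list of 34 clones had 4 called positive and 1 negative (13 adjusted over the list alone) and a cameraPR adjusted p of 0.0277. This call was lost with an estimated correlation, where the adjusted p = 0.367, and with gene means, where the adjusted p = 0.974. The means of eno1, eno2 and gpc3 lay near 0, at -0.04, 0.02 and -0.01. Without its largest gene the median of the list turned from 0.06 to -0.02.

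In all, 66 clones (1.2%) passed for L2, 38 positive and 28 negative, and only 8 of them were named. Clones of the same gene shared their L2 in part, with an intraclass correlation of 0.321 (95% bootstrap interval 0.142 to 0.414). The permutation p was 0.0001, the smallest the shuffles can give. The SD within genes was 0.092, against 0.112 over all clones. Of the 624 clones used, 115 were of alpha-tubulins, which may share hybridisation signal, and the agreement without them was not tested. The arrays themselves shared little between dye orientations. Forward H99 arrays correlated with each other at 0.33 to 0.62 and the reversed pair at 0.57, but forward with reversed arrays at only -0.17 to 0.22. The count of 66 was 14, 19 and 32 without H99 arrays 1, 2 and 3, 101 without B73 array 3, and 7 with each clone's own variance. It rose to 310 with arrays scaled to one spread and to 430 after quantile normalization. The difference between the parents' counts is not itself a test. The additive parameter tests clone by clone whether L1 and L2 differ, and so whether the inbreds differ. It does not test whether the hybrid lies farther from B73 than from H99.

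**Figure D2:**
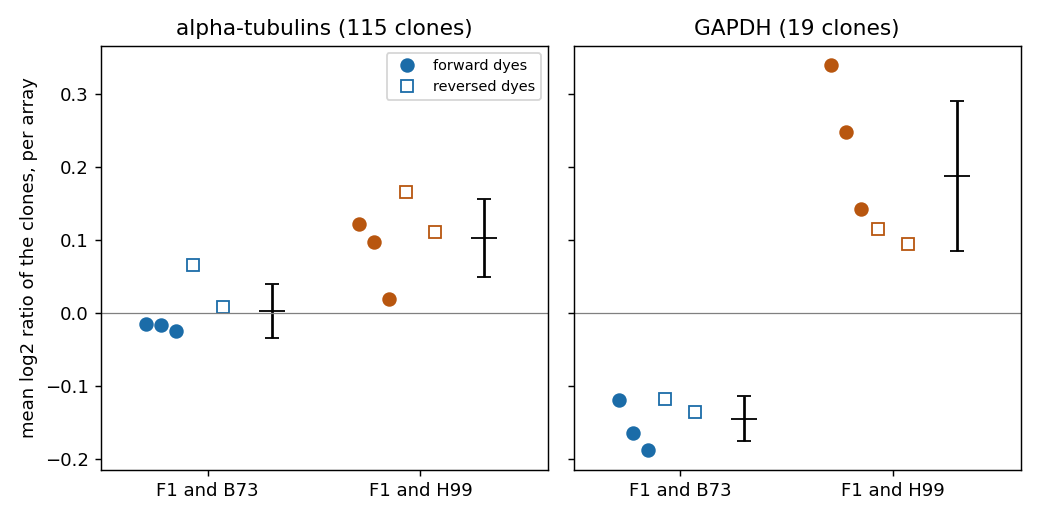
Mean log2 ratio of 115 alpha-tubulin clones of 5 genes (left) and 19 glyceraldehyde-3-phosphate dehydrogenase (GAPDH) clones of 3 genes (right) on each array. Filled circles are forward and open squares reversed dye orientation, and bars give the mean and SD over 5 arrays. The mean of the GAPDH clones lay below 0 on all 5 B73 arrays and above 0 on all 5 H99 arrays.

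The dominance parameter d, the mean of L1 and L2, measures the distance of the hybrid from the middle of its parents. A clone of sam2 lay farthest on the negative side among named clones with one sign on all 10 arrays, at -0.63 ± 0.064 (SE; limma adjusted p = 2.96e-06), with L1 of -0.98 and L2 of -0.28. On the positive side, single clones of the alpha-tubulins tua4 and tua3 lay at 0.26 ± 0.044 and 0.23 ± 0.051 (SE) and one of kn1, a homeobox gene of meristems, at 0.22 ± 0.039 (SE). Other clones of these genes did not all share the sign: 42 of 57 clones of tua4, 9 of 16 of tua3 and 7 of 11 of kn1 were positive, and 15 of 32 of sam2 were negative. Another clone of tua3, without one sign on all arrays, was called at -0.605. The means over clones were 0.065 for tua4, -0.012 for tua3, -0.008 for kn1 and -0.03 for sam2. PIP2-1 passed as a gene mean, with d = -0.16 ± 0.038 (SE, limma adjusted p = 0.0078) and all 6 clones negative. Its mean L2 was only -0.03, so its d, and its a given below, rest mostly on its L1. The tubulins and actins had 37 positive and 13 negative clones among 121 (54 called adjusted over the list alone) and a cameraPR adjusted p of 0.004, which was lost with an estimated correlation (adjusted p = 0.727). In all, 1352 clones (25.2%) passed, 671 positive and 681 negative, and the intraclass correlation within genes was 0.024 (permutation p = 0.14). The count fell to 721, 853 and 849 without B73 arrays 1, 2 and 3 and to 789 without H99 array 1. It was 850 with arrays scaled to one spread, 704 with each clone's own variance and 2278 with array weights.

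The additive parameter a, L2 minus L1 divided by 2, compares the inbreds with each other through the hybrid. Of the 3 GAPDH genes, 2 passed by gene mean. Hybridisation signal shared between these genes was not tested, so the 2 may not be independent. All 10 clones of GPC1 had a positive a, with a gene mean of 0.20 ± 0.041 (SE; limma adjusted p = 0.00698), and gpc2 had 0.15 ± 0.038 (SE; limma adjusted p = 0.0129), with 5 of 7 clones positive. Their mean L1 and L2 had opposite signs, but of these only L1 of GPC1 passed. The third gene, gpc3, had a = 0.05 ± 0.035 (SE; limma adjusted p = 0.281) over 2 clones. Also by gene mean, PIP2-1 had a = 0.13 ± 0.038 (SE; adjusted p = 0.0248), and adh1 had -0.12 ± 0.040 (SE; adjusted p = 0.0455), each with one sign in all clones. Adjusted over the named genes alone, adh1 did not pass (adjusted p = 0.0709), and 22 genes did in place of 27. The single clones of rop5, a small GTPase, and of ZAG3 lay at -0.33 ± 0.061 and -0.21 ± 0.038 (SE). One clone of CaM1, a calmodulin, lay at -0.25 ± 0.052 (SE), but only 5 of its 9 clones were negative, and their mean of -0.04 did not pass (limma adjusted p = 0.473). The list of glycolysis and fermentation had 10 positive and 4 negative clones among 34 (14 adjusted over the list alone; cameraPR adjusted p = 0.0371), and that of tubulins and actins 26 and 6 among 121 (41 adjusted over the list alone; cameraPR adjusted p = 0.0487). Both calls were lost with an estimated correlation, each with an adjusted p = 0.484. In all, 1089 clones (20.3%) passed, 490 positive and 599 negative, with an intraclass correlation of 0.096 (95% bootstrap interval 0.012 to 0.182; permutation p = 0.0001). Without B73 arrays 1, 2 or 3 the count was 593, 693 or 665, and without H99 arrays 2 or 3 it was 630 or 649. It was 470 with arrays scaled to one spread, 457 with each clone's own variance and 1983 with array weights. The parameters d and a both contain L1, with opposite signs, so their calls are not separate evidence. Of clones called for both, 196 were negative for d and positive for a, and 258 positive for d and negative for a. Only 5 were negative for both and 9 positive for both.

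The design text sorted genes by the ratio of d to the size of a, to ask whether the hybrid resembles one parent. Of the 1089 clones called for a, the 95% interval placed 561 (51.5%) in the dominance class, where the hybrid could not be told from one inbred. In 538 of these the hybrid lay closer to H99 and in 23 closer to B73, going by which of L1 and L2 was smaller in size. L1 spread more widely over clones (SD 0.229) than L2 (SD 0.112), which by itself puts more clones closer to H99. L1 was also not shared by clones of one gene (intraclass correlation -0.007), so the split does not show that H99 is dominant across genes. These classes, too, rest on the arrays as deposited. With the reversed H99 arrays turned, 659 of 1516 clones (43.5%) were dominant, 638 of them closer to H99 and 21 closer to B73, 303 were additive and 19 overdominant. With the reversed B73 arrays turned 0 of 2 clones were dominant, and with those of both inbreds turned no clone could be classed. A further 141 (12.9%) were additive, 9 partly dominant, 55 (5.1%) overdominant and 323 (29.7%) not resolved. Of the GAPDH clones, 5 of the 10 of GPC1 and 3 of the 7 of gpc2 were additive, and all 55 overdominant clones lay closer to H99. Apart from these, 884 clones were called for d and not for a. The hybrid lay beyond both inbreds by separate calls for L1 and L2 in 22 clones, of which 20 were negative, 2 positive and none named. With arrays scaled to one spread, 168 of 470 clones (35.7%) were dominant, 151 (32.1%) additive and 5 (1.1%) overdominant. After quantile normalization these were 256 (39.4%), 167 (25.7%) and 15 (2.3%) of 649. Overdominant clones numbered 25 with each clone's own variance and 120 with array weights. Without B73 arrays 1, 2, 3 or 5 the dominance class held 274, 342, 291 or 902, and without H99 arrays 2 or 3 it held 330 or 368. The additive class held 85, 81, 78 and 229 clones without H99 arrays 1, 2, 3 and 5, and the overdominant class 35 without H99 array 2.

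**Figure D3:**
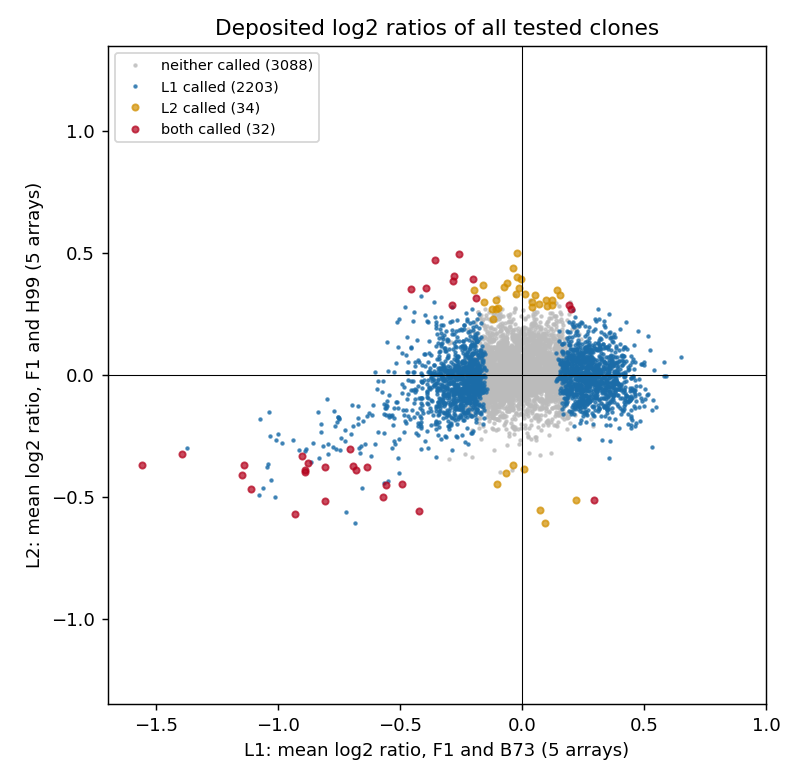
L1 (horizontal) against L2 (vertical) for 5357 clones, in log2 units, each the mean of 5 arrays. Colours mark clones called for L1, L2, both or neither; 32 were called for both, and 20 of these were negative for both.

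Across clones, L1 and L2 correlated with Pearson's r of 0.20 and Spearman's rho of 0.113, and 53.6% of the clones had one sign in both. Clones are not independent replicates. In 100 simulations with no genotype effect that kept the estimated dye effects, r averaged 0.062 and reached 0.093. The covariance was 0.00513 against a simulated 0.00029, a difference of 0.00484. Both comparisons share the RNA pool of the hybrid, which could not be split, so part of this excess may come from the shared pool. The simulated dye effects were estimated from the orientation of the arrays, which holds only if the reversed arrays had been turned before deposit. If they had not, a dye bias shared by both inbreds would lie in L1 and L2, and the simulation would miss it. With 1 dye orientation alone, r was 0.043 for the forward and 0.426 for the reversed arrays. It was 0.084 without H99 array 5 and 0.315 without H99 array 3. With the reversed arrays turned r was 0.075 for those of B73, -0.142 for those of H99 and 0.007 for both. Among calls, 20 clones were negative in both against 5.8 for independent lists, and 2 were positive in both against 8. With opposite signs, 9 were negative for L1 and positive for L2 against 7.9, and 1 was positive for L1 and negative for L2 against 5.9.

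Outside tubulins and glycolysis, no list passed in any of the 4 contrasts. The lowest adjusted p was 0.142, for the MADS-box and other inflorescence regulators in a, with 10 clones negative and 1 positive. It was 0.242 for water channels and transporters, 0.27 for kinases and signalling, 0.307 for oxidative stress, 0.312 for ribosomal proteins, 0.318 for cell cycle and DNA replication and 0.326 for chaperones and heat shock. For green tissue markers, which would report husk or leaf, it was 0.388, for methylation and the S-adenosylmethionine cycle 0.424, for HMG and other chromatin proteins 0.425 and for histones 0.542. Translation factors had 0.651, mitochondrial respiration 0.665, defence and wound genes 0.665, and sucrose and starch genes 0.755. In 15 of the 68 pairs of list and contrast the median, mean and test of a list differed in sign, and none of these pairs passed.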

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

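All tests of explanations in this part were chosen after the results they concern had been seen.

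The means of 2 of the 3 GAPDH genes had opposite signs against the 2 inbreds. The mean of 10 GPC1 clones had an additive parameter of 0.198 (adjusted p = 0.00698) and that of 7 gpc2 clones 0.154 (adjusted p = 0.0129), with every B73 array below 0 and every H99 array above 0. Not all clones shared this: 3 of 10 clones of GPC1 and 3 of 7 of gpc2 were positive for L1, and gpc3 had means of -0.12 for L1 and -0.01 for L2. One clone each of GPC1 at 0.344 (adjusted p = 0.00158) and of gpc2 at 0.252 (adjusted p = 0.00351) was called for L1 and L2 with opposite signs. The mean of 4 clones of Ann7, an annexin, was likewise opposite on all arrays, at 0.071, but its difference did not pass (adjusted p = 0.162). Over all 19 GAPDH clones the array means were -0.14 ± 0.031 for B73 and 0.19 ± 0.10 for H99 (SD, n = 5 each). For 115 alpha-tubulin clones the means were 0.003 ± 0.037 and 0.10 ± 0.054 (SD, n = 5 each). Both families were grouped after their values had been seen, so no test of these differences is given.

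For the positive H99 values of both families, a trend over print positions is argued against: the lower of both means, that of the alpha-tubulins, was 0.098 after the neighbours were subtracted. The range of L2 over all 5 alpha-tubulin genes was 0.201, since tua5 and tua6 lay at 0.02 and -0.07. The genes differed mainly on the forward H99 arrays, and on the reversed arrays all their means were positive and closer together. Cross-hybridisation that gives all 5 genes one value is thus argued against on the forward arrays and stays open on the reversed ones. It also stays open between tua4, TUA1 and tua3, which differed by only 0.056, and it was not tested for the GAPDH genes. Dye bias stays open too: both family means were above 0 in both orientations as deposited, but with the reversed H99 arrays turned the means would be -0.008 for the alpha-tubulins (SE 0.057) and 0.104 for GAPDH (SE 0.091). A candidate explanation that also stays open is a difference in transcript level between hybrid and inbred, which arrays of a single RNA pool per genotype cannot tell from a difference between pools.

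L1 values repeated between B73 arrays but differed between clones of one gene. Differences in gene expression as the whole cause are argued against by the intraclass correlation of -0.007. A print trend as the whole cause is argued against, since 1432 of 2235 clones were called both before and after the neighbours were subtracted. As part of the cause it stays open. Clones at the same position of the inferred print blocks had an intraclass correlation of 0.259 for L1, and successive clones correlated at 0.302. A shift of all B73 values as a block against the probe table is argued against by the correlation of L1 with L2. Over all clones with values it was 0.197 in the order given and at most 0.081 at any of 5399 other shifts. The highest intraclass correlation of L1 at another shift was 0.123, below the interval for L2. That bound cannot decide alone, since L1 in the right order need not agree within genes as well as L2. Other errors of order, differences between clone sequences or inbred alleles, a dye bias on reversed arrays not turned before deposit, and effects of channel intensity could be the cause and stay open, as channel intensities were not analysed here.

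Forward and reversed H99 arrays hardly correlated across clones, with r of 0.03 between their means. A dye bias of clones shared by both inbreds stays open, because its test depends on whether reversed arrays had been turned. The dye parts of both inbreds correlated at 0.068 if all had been, at 0.001 if only those of B73, at -0.218 if only those of H99 and at 0.258 if none. Deposition of the reversed H99 arrays in the opposite direction could not be settled: over 70 genes, gene means on both orientations correlated at 0.30 when weighted by clones, with a 95% bootstrap interval of -0.1 to 0.6, and at 0.119 unweighted, with one sign in 38 genes. If it were so, L2 would have 41 calls in place of 66, d 666 in place of 1352 and a 1516 in place of 1089.

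Single arrays stood apart from the others of their inbred in 14 of 215 groups of values. Chance gives about 1 in 20 for unselected values. The named clones were selected for stable signs or a low p, so the share cannot be judged against that rate. The groups were values of named clones and, for each inbred, the SD and the share of missing spots of its arrays. All 14 were for named clones. The gap to the nearest array, as a share of the range, was 0.846 for 9-24, 0.719 for pep7, 0.754 for sam2, 0.931 for eno1 and 0.793 for mbd105, all on H99 array 3. On H99 array 4 it was 0.863 for PEAMT, 0.731 for elfa2 and 0.727 for gst11. On H99 array 1 it was 0.81 for MCM6, 0.749 for a clone of TUA1 and 0.777 for sbe1, and on H99 array 5 it was 0.753 for another clone of TUA1. For B73 it was 0.88 for INO1 on array 4 and 0.792 for LOC606466 on array 3. No explanation was tested for these.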

How the results depend on the processing

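Tests on single spots, subtraction of neighbours, 1 dye orientation alone, turned reversed arrays and lists on gene means were chosen after the data were seen; the other alternatives were planned. Centring, filters on missing values and robust variances kept all counts within 1.5 times.

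With arrays scaled to one spread, L1 had 1142 calls, L2 310, d 850 and a 470, with 168 dominant, 5 overdominant and 136 unresolved clones. Quantile normalization gave 1338 for L1, 430 for L2 and 649 for a, with 256, 15 and 198 clones in these classes. Each clone's own variance gave 7 for L2, 704 for d and 457 for a, with 233 dominant, 16 partly dominant, 25 overdominant and 80 unresolved clones. Array weights gave 356 for L2, 2278 for d and 1983 for a, with 1168 dominant, 222 additive, 46 partly dominant and 120 overdominant clones. A dye term gave 156 for L2 and 19 partly dominant clones, and a threshold of 0.10 gave 177 for L2. The 99% interval left 35 additive, 0 partly dominant and 31 overdominant clones and 613 unresolved. The cause was not tested.

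Among 16048 single spots, 6001 passed for L1, 126 for L2, 3254 for d and 2653 for a, with 1350 dominant, 339 additive, 22 partly dominant, 137 overdominant and 805 unresolved; there are 3 spots per clone. Forward arrays alone gave 537 for L2 (230 positive, 307 negative) and 2196 for a, with 1120 dominant, 397 additive, 80 partly dominant, 86 overdominant and 513 unresolved clones. Reversed arrays alone gave 748 for L1, 290 for L2 and 164 for a (134 positive, 30 negative), with 95 dominant, 27 additive, 2 partly dominant, 32 overdominant and 8 unresolved clones and r of 0.426 between L1 and L2. These fits use fewer arrays, which by itself tends to lower counts, but L2 rose above its 66 calls in both. Of those 66 clones, 63 were called with forward arrays alone and 28 with reversed arrays alone. Forward and reversed H99 arrays hardly correlated, but the cause of the changed counts was not tested.

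With the reversed arrays of H99 turned, L2 had 41 calls (4 positive, 37 negative) and d 666, with 303 additive, 47 partly dominant, 19 overdominant and 488 unresolved clones and r of -0.142. With those of B73 turned, L1 had 0 calls, L2 13, d 2 and a 2, and with those of both inbreds all had 0, with r of 0.007. Of the 123 called values of named clones below, 95, 2 and 0 stayed called in these 3 settings, and of the 5 calls of lists 1, 3 and 0. Chaperones and heat shock were called negative for L2 and d with the reversed arrays of H99 or of both inbreds turned. Which setting holds is not known.

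Leaving out 1 array gave 1398 (without B73 array 3) to 2476 (B73 5) calls for L1 and 14 (H99 1) to 101 (B73 3) for L2. It gave 721 (B73 1) to 1731 (B73 5) for d and 593 (B73 1) to 1498 (B73 5) for a. Dominant clones ranged from 274 (B73 1) to 902 (B73 5), additive from 78 (H99 3) to 229 (H99 5) and partly dominant from 3 (H99 2) to 22 (B73 5). Overdominant clones ranged from 35 (H99 2) to 67 (B73 4) and unresolved ones from 156 (H99 3) to 391 (H99 5); r ranged from 0.084 (H99 5) to 0.315 (H99 3). With the replicate number as a block, d had 1392 and a 828 calls, but the numbers do not pair arrays (consensus correlation -0.018).

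Of 5 calls of lists, 1 held with an estimated correlation, 0 with gene means and 5 with a dye term. Subtraction of neighbours gave 6 calls, the added one for water channels in a (adjusted p = 0.00397).

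Of 123 called values of named clones, chosen for one sign on every array or, in lists, for the lowest p, 1184 of 1227 comparisons under alternatives fixed beforehand, other than leaving out an array and the looser threshold, stayed called and 43 did not. Leaving out an array kept 1179 of 1221. Added alternatives other than turned arrays kept 288 of 366. With reversed arrays alone 56 of 120 stayed called, 63 were lost and 1 changed sign. The L1 of a gst41 clone, -0.32 with 2 positive and 3 negative arrays, turned to 0.039 when neighbours were subtracted and to 0.086 with reversed arrays alone, where it was not called (adjusted p = 0.714 and 0.501). Signal over background is not given in the values analysed here.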

Other observations

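The tests with turned or divided arrays were chosen after the counts had been seen. Turning the sign of arrays within an inbred gives only 16 patterns, too few for a share under 0.05. For L1 the actual signs gave 2235 calls and the highest other pattern 676, when B73 array 5 was turned, so that 1 pattern was as large. For L2 the actual signs gave 66 calls and the highest other pattern 41, when both reversed H99 arrays were turned; again 1 was as large. For d, 1 of 100 drawn patterns reached 1352, and the highest other had 1171, with H99 arrays 2, 3 and 4 turned. For a, 1 of 100 divisions drawn from 126 reached 1089, and the highest other had 264. The pattern or division as large was in both cases the actual one. For a, no other drawn division came near the actual count, which argues against a chance division of the arrays. For d the test cannot decide, since the highest other pattern left all B73 arrays unturned and so kept L1. These tests, too, cover only arrays of the same RNA pools.

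A dye term called 214 clones for dye orientation, 103 positive and 111 negative. This term measures dye bias only if the reversed arrays had been turned before deposit, which is not known. Clones at the same position in the 8 inferred print blocks shared values, with an intraclass correlation of 0.259 for L1 and 0.157 for L2 over 675 positions. After neighbours were subtracted, clones of one gene had an intraclass correlation of 0.039 for L1 (permutation p = 0.04) and of 0.357 for L2 (permutation p = 0.0001, the smallest possible).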
